A study of Homo sapiens with 2 samples.

How the data were processed

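Total RNA was extracted with TRIzol from 2 cultures of C81 cells, converted to biotin-labelled cRNA and hybridised to Affymetrix arrays of 1 colour, with 1 array for the vector control and 1 for EBP1, per the labels. The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The version of MAS5 and its background and scaling settings are not given in the sources used here. The values show that both arrays had been brought to a common scale before they were deposited, since the mean intensity without the lowest and highest 2% was 250.1 on both arrays. They run from 0.133 to 16705 on the control array and from 0.211 to 18606 on the EBP1 array. No other columns of sample values were present or used.

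Each array holds 22277 probe sets, of which 62 are controls. Of the 22215 others, 19064 name 1 gene in the platform's annotation table, 1043 name several and 2108 are not listed there; the last 2 kinds were left out of counts of genes and of gene lists. Symbols were updated through the gene identifier in a table of the GRCh38.p14 assembly, which held 19052 of the 19064; the other 12 kept the platform's symbol. This gave 11963 genes, 4310 of them with more than 1 probe set. The table was used only for names, chromosomes and neighbouring genes, and no coordinates are given because no genome build is named for the array.

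The values were used as deposited, with no further scaling. Signals below a floor were raised to it, the floor being the median of all signals that are not controls over both arrays (86.6). A gene was measured when at least 1 array reached the floor, which left 7544 genes, of which 6135 were at or above the floor on both arrays. A gene with several probe sets is represented by the one with the highest mean floored log2 signal, a choice that does not look at its ratio. Log2 ratios are the array labelled EBP1 over the vector control, and a ratio of a gene below the floor on 1 array is a bound, written as at least. Flooring shrinks ratios of dim genes, and probe sets whose names end in _s_at or _x_at can bind transcripts of several genes. The number of arrays limits the precision: with 1 per group there is no replicate error, and counts past 2-fold describe these 2 arrays only. Spread was taken from probe sets of the same gene.

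A total of 34 gene lists was fixed before the data were examined, together with the floor, the threshold of 2-fold, the rule for named genes and all alternatives but 1. For each list with at least 5 measured members, the median log2 ratio was set against 10000 random lists of the same size, drawn from the measured genes in 10 bins of mean log2 signal. The percentile among them is a description of these arrays and not a p-value, since genes are not replicates. The genes named are PA2G4 with every probe set; the 10 highest and 10 lowest ratios among genes above the floor on both arrays; in each direction the 5 brightest genes that were below the floor on 1 array and at least 2-fold above it on the other; in each direction the 5 genes whose measured probe sets were all past 2-fold by the widest margin; and up to 4 members of each assessed list with the largest ratios, or up to 2 where no member was past 2-fold. Cancer-testis families, Y-linked genes beyond those, and the span of chromosome 1 were chosen after their values were seen. Neighbouring genes were examined in windows of 30 measured genes along each chromosome, with the 95th percentile of the largest window in 1000 shuffled gene orders (0.49) as the bound.

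Alternatives were an equal median on both arrays, quantile normalization, a loess fit of the ratio on mean signal with a span of 0.3, floors at the 25th and 75th percentiles, no floor with a pseudocount of 16, the median over a gene's measured probe sets, removal of probe sets ending in _s_at or _x_at, and thresholds of 1.5-fold and 3-fold. Removal of the genes of the chromosome 1 span was added after the data were seen.

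The steps were tested on simulated data for this comparison, with 7110 measured genes, a noise SD of 0.34 in the log2 ratio and 200 changed genes. The changed genes were drawn only from genes at or above the median signal of the measured genes, and every probe set had the same noise. In the data the SD of a single probe set's log2 ratio was taken from pairs of the same gene. It was 0.51 with a floor at the 25th percentile and 0.24 at the 75th. The shares that follow are therefore too favourable for dim genes. The simulated noise also left out any spread between cultures or arrays, so the shares can be too favourable for bright genes as well. In the data the log2 ratios of all measured genes, changed ones included, had a robust SD of 0.50. Noise was drawn independently for each probe set, so the share of unchanged lists does not cover genes that vary together. Of 50 genes each, 58.0% changed 2-fold, 98.0% changed 3-fold and 100% changed 4-fold or 8-fold were past the threshold, as were 20 of 6910 unchanged genes (0.289%). Of 100 unchanged lists, 6 lay outside the central 95%, and a list of 20 genes shifted by 0.5 lay at percentile 100. In 6000 simulated genes the search for neighbours gave 0 runs in an unchanged order and recovered 100 of 100 genes of a planted run. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.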

Results

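Expression was measured in C81 cells, a hormone-independent human prostate cancer line that descends from LNCaP. The series description names C81 for both cultures, while the sample titles name only LNCaP and the source label of the EBP1 culture gives the line as 81. Cultures were selected as pools after transfection with the empty CMV6 vector or with an expression plasmid for EBP1, and RNA was taken in logarithmic growth. EBP1, the product of PA2G4, is a protein that binds the receptor ERBB3 and acts as a corepressor of the androgen receptor. There was 1 array for the vector control and 1 for EBP1, so no value below has a replicate error and no p-value can be given. The labels present the comparison as a question about what EBP1 does in hormone-refractory prostate cancer.

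Each array held 22277 probe sets. The mean signal trimmed by 2% was 250.1 on both arrays, while the median of the probe sets that are not controls was 77.8 on the vector control array and 94.0 on the EBP1 array. A floor of 86.6 was reached by 47.9% of these probe sets on the control array and by 52.1% on the EBP1 array. Across all these probe sets the log2 signals of both arrays had a Pearson correlation of 0.89 (across probe sets, which are not independent replicates). The ratio of 3′ to 5′ signal, a measure of RNA integrity, was 1.18 on the control array and 1.35 on the EBP1 array for ACTB, and 0.944 and 0.976 for GAPDH.

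PA2G4, the gene carried by the plasmid, was not raised on the EBP1 array. Its brighter probe set gave a signal of 1007 on the control array and 1115 on the EBP1 array (1.11-fold), and the other gave 636 and 621 (0.977-fold). Whether the plasmid's transcript holds the part of PA2G4 that these probe sets cover is not given in the sources used here, so these values may leave that transcript out. Because the signal of PA2G4 does not bear out the label, the array is called the array labelled EBP1 from here on, and every direction below rests on that label.

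On the array labelled EBP1, androgen-induced genes were lower and genes for DNA replication and mitosis were higher than on the vector control array. KLK3, which encodes prostate-specific antigen, was 44.4-fold lower, from a signal of 9970.5 to 225. The lists of hypoxia and glycolysis genes, of cholesterol and fatty acid synthesis and of ATF4 and endoplasmic reticulum stress genes were lower too. Metallothioneins were higher, and so was a list of genes of TGF-beta and BMP signalling, led by ID1, ID2 and ID3, which encode inhibitors of helix-loop-helix transcription factors. The median of that list lay inside the range of random lists with a floor at the 25th percentile or with no floor. Of 7544 measured genes, 304 were at least 2-fold higher and 268 at least 2-fold lower on the array labelled EBP1.

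These 572 genes are 7.58% of the measured genes. From 4775 pairs of probe sets of the same gene, the robust SD of a single probe set's log2 ratio was 0.34. The absolute difference within a pair had a 95th percentile of 1.15, which is past 2-fold. This spread covers probe and hybridisation noise but not the spread between cultures or arrays. Of 209 genes past 2-fold with several measured probe sets, 187 (89.5%) had all of them on the same side, and 77 (36.8%) had all of them past 2-fold. The split between directions depends on the scaling: with the array medians set equal, which moves the median log2 ratio of the measured genes from 0.07 to -0.18, 148 genes were higher and 541 lower (21.5% higher against 53.1%).

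**Figure D1:**
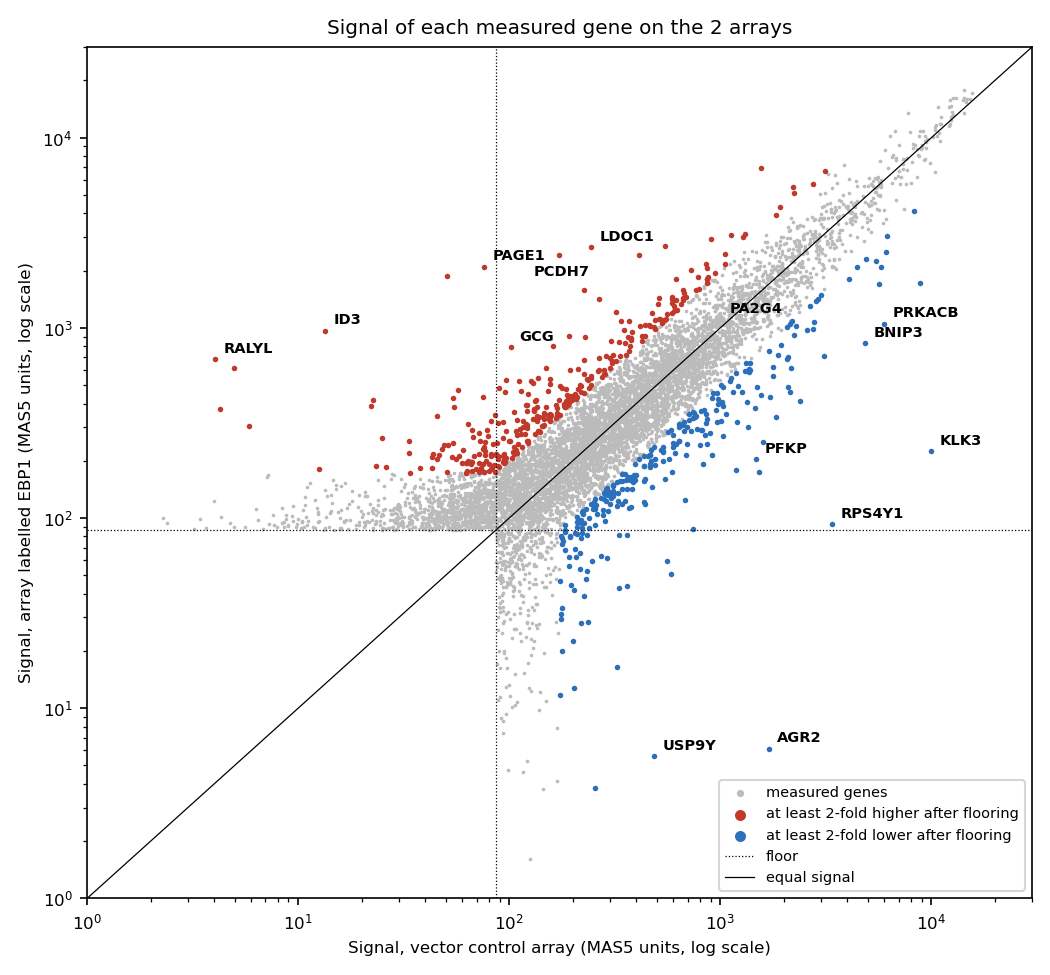
Each point is a measured gene, with its signal on the vector control array on the horizontal axis and on the array labelled EBP1 on the vertical axis, both in MAS5 units on a log scale. Dotted lines mark the floor of 86.6, and coloured points are the 304 genes at least 2-fold higher and the 268 at least 2-fold lower after signals under the floor are raised to it. KLK3 lies far below the line of equal signal, and PA2G4 lies on it.

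Among genes seen above the floor on both arrays, the largest ratios in favour of the array labelled EBP1 were those of PCDH7, a protocadherin (171 to 2416, 14.1-fold, with another probe set at only 1.88-fold), and LDOC1 (245 to 2659, 10.9-fold). They were followed by GCG, the glucagon precursor (7.74-fold), UGT2B28, which glucuronidates steroids (6.95-fold), the secreted phospholipase PLA2G2A (5.90-fold), STAC (5.49-fold), the nucleosome-binding HMGN5 (5.43-fold), the histone chaperone ANP32E (5.33-fold), the antisense RNA PITX1-AS1 (4.99-fold) and the initiation factor EIF1B (4.90-fold). In the other direction, KLK3 was followed by the Y-linked ribosomal protein gene RPS4Y1 (3403 to 92.9, 36.6-fold lower), AKAP9 (8.68-fold, with another probe set at 2.63-fold), RIPOR2 (8.51-fold, with another at 2.09-fold) and the phosphofructokinase gene PFKP (7.27-fold). MMP7, a matrix metalloprotease, was 6.60-fold lower, NDRG1 6.35-fold, the mitophagy receptor gene BNIP3 5.83-fold, CCNG2 5.81-fold and PRKACB, a catalytic subunit of protein kinase A, 5.68-fold.

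Other genes were above the floor on 1 array and below it on the other, which gives only a bound. PAGE1 was at least 24.3-fold higher on the array labelled EBP1 and MAGEC2 at least 21.7-fold; both belong to the cancer-testis genes, which most adult tissues do not express. ID3 was at least 11.2-fold higher, RALYL at least 7.88-fold and the cancer-testis gene CTAG2 at least 7.12-fold, with another probe set of CTAG2 at 2.03-fold. AGR2, which encodes a protein disulfide isomerase of secretory epithelia, had a signal of 1699 on the control array and was at least 19.6-fold lower. COXFA4L2 was at least 6.74-fold lower, PTPRR 6.45-fold, the Y-linked USP9Y 5.59-fold and PDK1, a kinase that inhibits pyruvate dehydrogenase, 4.18-fold. Genes whose measured probe sets all passed 2-fold included ANP32E, ATP1B1 (4.43-fold), MSH6 (3.42-fold), NEK2 (227 to 679) and TBCE (2.82-fold) on the higher side, and KLK3, PRKACB, TMPRSS2 (4.66-fold), BNIP3 and PEG3 (4.29-fold) on the lower side.

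Of 34 gene lists, 29 had at least 5 measured members, and the medians of 14 lay outside the central 95% of 10000 random lists matched on size and signal, 8 on the low and 6 on the high side. Of 15 measured androgen-induced genes, 13 were lower and 5 of these at least 2-fold, with a median log2 ratio of -0.68, below all random lists. Besides KLK3, NDRG1 and TMPRSS2, KLK2 was 3.74-fold lower. Of 11 androgen-repressed genes, 7 were higher, 5 of them at least 2-fold, and 4 were lower, 0 of them by that much (CAMK2N1 was lowest, with a log2 ratio of -0.74), with a median of 0.97, above all random lists. ID3, UGT2B28, ID1 (at least 4.47-fold) and the opioid receptor gene OPRK1 (at least 3.96-fold) led this list, and ID1 and ID3 are also in the list of TGF-beta and BMP target genes. Without probe sets that can bind several transcripts, among them those used for ID1, ID3, UGT2B28 and UGT2B15, the median of the androgen-repressed genes was 0.21, inside the random range. Prostate antigens had a median of -0.98 over 7 members (percentile 0.015, mean -0.44), of which 4 were lower and 3 higher. FOLH1, encoding prostate-specific membrane antigen, was 2.57-fold lower, ACP3 2.18-fold and HPN 2.11-fold, whereas STEAP1, EPCAM and RLN2 had log2 ratios of 0.22, 0.53 and 0.70. The median was -0.37 with a floor at the 25th percentile of all signals and -0.29 with no floor. Without those same probe sets, and with a floor at the 75th percentile of all signals, fewer than 5 antigens were measured and this list could not be assessed.

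The lists of mitosis genes and of E2F and DNA replication genes were higher on the array labelled EBP1. All 33 measured mitosis genes had a positive log2 ratio and 13 were at least 2-fold higher, with a median of 0.93, above all random lists. The kinase genes BUB1 (3.09-fold) and NEK2 (log2 ratio 1.58), the kinetochore gene CENPF (2.60-fold) and CDC20 (2.51-fold) led this list, though the other probe sets of BUB1 and CENPF reached log2 ratios as low as 0.39 and 0.41. Of 30 E2F and DNA replication genes, 27 were higher and 7 at least 2-fold, with a median of 0.84, also above all random lists. MCM6 (2.28-fold), TK1 (2.17-fold), CCNE2 (2.03-fold) and RFC4 (2.03-fold) were the largest, and these 4 were no longer past 2-fold with the array medians set equal. G1 cyclins and CDK inhibitors lay inside the random range, with a median of 0.12 and a mean of -0.13. CDKN1C was at least 2.72-fold higher, with another probe set at a log2 ratio of only 0.30, and RBL2, a relative of the retinoblastoma gene, was 2.68-fold lower.

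Several metabolic and stress lists were lower. Of 23 hypoxia and glycolysis genes, 21 were lower and 10 at least 2-fold, with a median of -0.82, below all random lists; PFKP, BNIP3, PDK1 and NDRG1, which is also in the androgen-induced list, led it. Cholesterol and fatty acid synthesis genes had a median of -0.54 (percentile 0.01), with 14 of 17 lower and 5 at least 2-fold. Among them were the desaturase gene FADS2 (3.33-fold), HMGCS1 of the mevalonate pathway (2.52-fold), the transcription factor gene SREBF2 (2.29-fold) and INSIG1 (2.23-fold). Without probe sets that can bind several transcripts the median of this list was -0.32, inside the random range. Of 24 genes of ATF4 and endoplasmic reticulum stress, 19 were lower and 3 at least 2-fold, with a median of -0.46 (percentile 0.01): DDIT4 (2.78-fold), the cystine transporter gene SLC7A11 (2.35-fold) and TRIB3 (2.11-fold). These 3 are known as targets of ATF4, and the list was not split into its parts. Of the genes of endoplasmic reticulum stress, HSP90B1, HERPUD1, SEL1L, DNAJB9, HSPA5, CALR and PDIA6 had log2 ratios of -0.94, -0.73, -0.54, -0.48, -0.45, -0.41 and -0.20. PDIA4, XBP1 and SDF2L1 were at 0.57, 0.27 and 0.01, and another probe set of HSP90B1 was at -0.01. Heat shock genes had a median of 0.45 over 11 members (percentile 99.6), with CRYAB at least 3.12-fold and HSPB1 1.74-fold higher; this list was inside the random range under 3 of 8 alternatives, among them the median over all probe sets of a gene (0.28).

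All 7 measured metallothioneins were higher, with a median of 0.93 (percentile 99.97); MT1X was 2.51-fold and MT1F 2.09-fold higher, and the family's near-identical transcripts share probes. All 8 measured members of the list of TGF-beta and BMP target genes, which was drawn up with some ligand genes too, were higher, with a median of 0.98, above all random lists. The list has 18 members on the array, and TGFBI, CCN2 and PMEPA1 were below the floor on both arrays. Of these, 4 were past 2-fold: ID3, ID2 (4.82-fold), ID1 and BAMBI, a BMP pseudoreceptor gene (2.94-fold). The median of this list depends on the settings: it was 0.35 after quantile normalization, 0.21 with equal array medians and, with a floor at the 25th percentile, 0.37 and inside the random range. Interferon-stimulated genes had a median of -0.28 (percentile 0.04), with 17 of 22 lower; with a floor at the 75th percentile 8 members were measured and the median of -0.27 was inside the random range. The antigen-presenting HLA-C was 2.97-fold and HLA-B 2.85-fold lower, although a further probe set of HLA-C had a log2 ratio of 0.17, whereas IFITM1 was 3.26-fold higher. The list of ERBB receptors and ligands, which also holds regulator genes such as LRIG1 and RNF41, had a median of -0.55 (percentile 0.31, mean -0.37), with 5 of 9 members lower and 4 higher. Its receptor and ligand genes went both ways. EGFR, ERBB2 and HBEGF had log2 ratios of -1.54, -1.01 and -0.55, and ERBB3, EGF, NRG1 and TGFA of 0.09, 0.48, 0.75 and 0.83, those of HBEGF, NRG1 and TGFA being bounds. LRIG1 was 3.41-fold, EGFR 2.90-fold and ERBB2 2.02-fold lower, and the ligand gene TGFA at least 1.78-fold higher. ERBB2 was no longer past 2-fold after quantile normalization, after loess or with no floor. The direction of the ERBB list median turned under 3 alternatives, the largest value being 0.48 without probe sets that can bind several transcripts, where EGFR itself had a log2 ratio of 0.33.

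**Figure D2:**
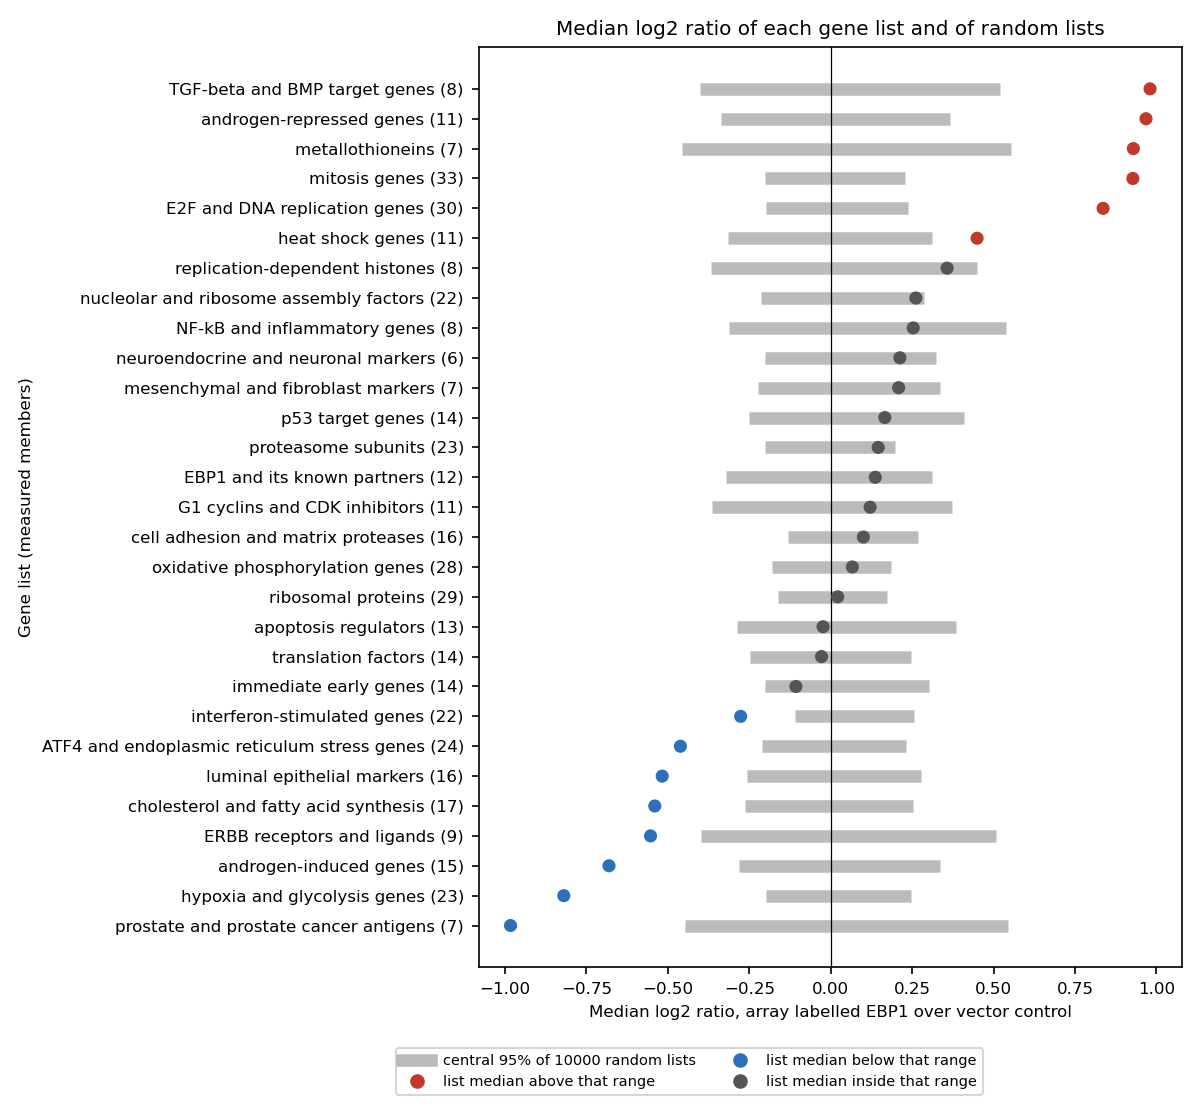
For each assessed list the point gives the median log2 ratio of its measured members (number in brackets), array labelled EBP1 over vector control, and the grey bar the central 95% of medians of 10000 random lists. The 14 coloured points lie outside their bar, 8 below it and 6 above it.

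**Figure D3:**
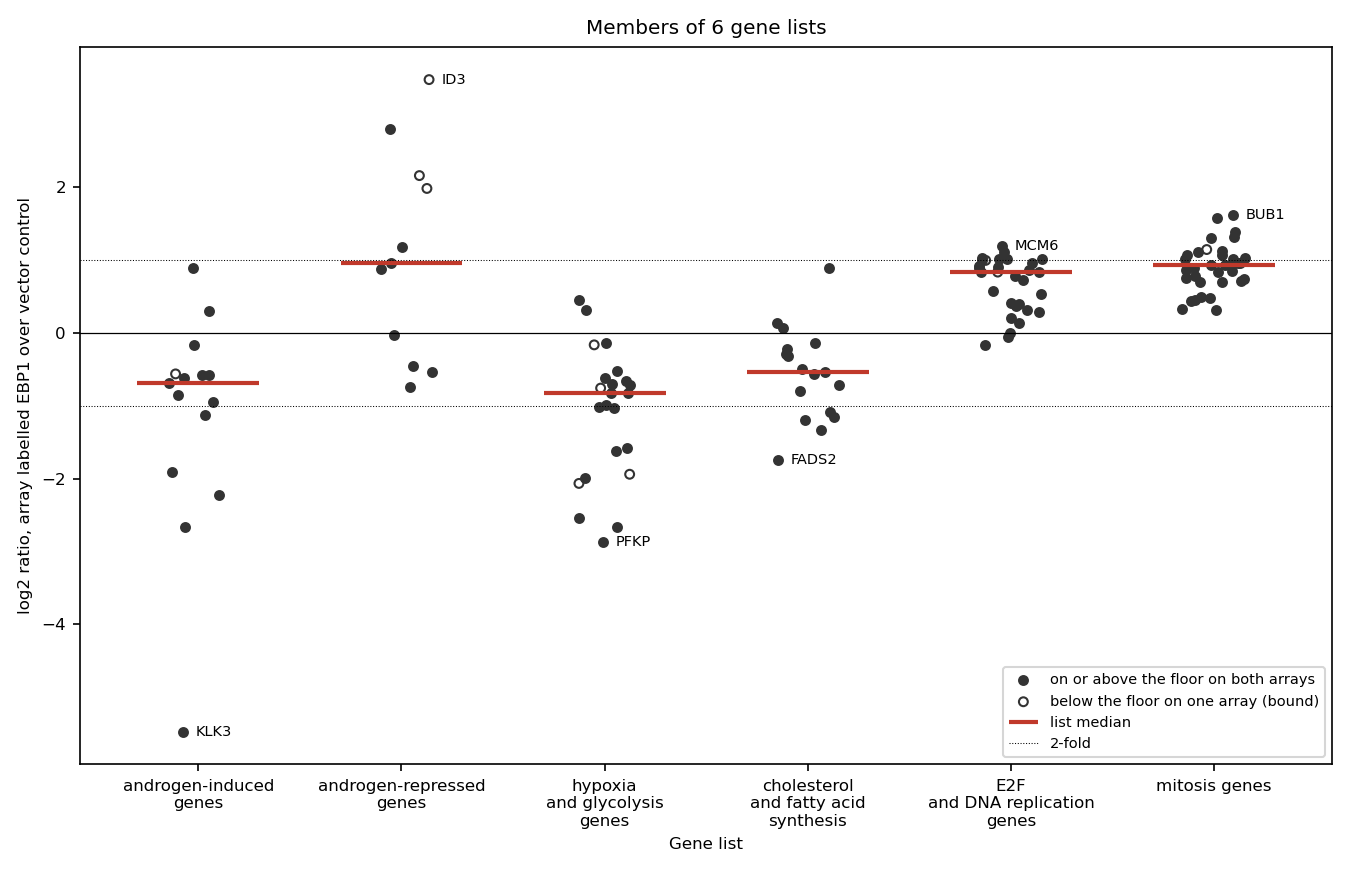
Each point is a measured member of the list named on the horizontal axis, with its log2 ratio of the array labelled EBP1 over vector control on the vertical axis; open points are below the floor on 1 array and give a bound, red lines are list medians and dotted lines mark 2-fold. All 33 mitosis genes lie above 0, and 21 of 23 hypoxia and glycolysis genes lie below it.

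Luminal epithelial markers had a median of -0.52 over 16 members (percentile 0.01, mean -0.40), of which 10 were lower and 6 higher. The claudin genes CLDN3 (2.76-fold) and CLDN4 (2.62-fold) and the prostate homeobox gene HOXB13 (2.13-fold) were lower, and ELF3 was 2.44-fold higher, with EPCAM, FOXA1 and CDH1 at log2 ratios of 0.53, 0.26 and 0.07. Neuroendocrine markers (median 0.21, mean -0.10) and mesenchymal and fibroblast markers (0.21) lay inside their random ranges; ENO2, which is also a glycolytic gene, was at least 3.83-fold lower and FN1 was 1.87-fold higher, with another of its probe sets at a log2 ratio of -0.64. Basal markers, leukocyte markers, endothelial markers, Wnt target genes and markers of androgen-receptor-negative prostate lines had fewer than 5 measured members and were not assessed, with 3, 4, 1, 4 and 4. Among these members 2 were past 2-fold, both named here after their values were seen: the Wnt-related transcription factor gene LEF1, at least 4.33-fold higher, and EGFR, lower as given above. Of the 15 markers of androgen-receptor-negative lines on the array, 11 were below the floor on both arrays and so have no ratio, and of the 4 measured 0 were at least 2-fold higher on the array labelled EBP1.

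The remaining lists lay inside their random ranges. EBP1 and its known partners had a median log2 ratio of 0.14, with ILF2 2.71-fold higher. Ribosomal proteins (0.02), translation factors (-0.03), oxidative phosphorylation genes (0.07), proteasome subunits (0.15), histones (0.36), NF-kB and inflammatory genes (0.25) and apoptosis regulators (-0.02, mean 0.05) had 0 members past 2-fold. Nucleolar and ribosome assembly factors were near the upper edge (0.26, percentile 96.2), with WDR12 2.34-fold higher. Among p53 target genes (0.17) the growth factor gene GDF15 was 5.15-fold and SESN1 2.04-fold lower. Immediate early genes had a median of -0.11, with DUSP5 at least 3.73-fold higher, KLF4 at least 2.51-fold lower (another probe set at a log2 ratio of only -0.17) and DUSP1 2.26-fold lower. Cell adhesion and protease genes had a median of 0.10 and a mean of -0.12, with MMP7 the only member past 2-fold. Ribosomal proteins changed sign under every other scaling. With the array medians set equal, the medians of the lists of EBP1 partners, G1 cyclins, ribosomal proteins, nucleolar factors, oxidative phosphorylation, proteasome, NF-kB, p53 targets and cell adhesion changed sign, and each list stayed inside its random range. Those random ranges were rescaled with the lists.

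Part of the higher genes lie together on chromosome 1. From SEC22B to ZNF692, the last measured gene of the chromosome, 332 of 365 measured genes (91.0%) had a positive log2 ratio, with a median of 0.62, against a median of 0.01 over the 419 genes from NOC2L to NOTCH2 on the rest of the chromosome and 0.05 over 6751 genes of other chromosomes. Chromosome 2 stood above the rest of these with a median of 0.27 over 471 genes, against -0.03 to 0.11 for the 21 others. This span holds 95 of the 304 genes at least 2-fold higher (31.3%), among them ANP32E, ATP1B1, NEK2, TBCE, CENPF, ILF2 and ELF3. Without its genes, an alternative chosen after the data were seen, 209 genes were at least 2-fold higher and 265 lower, and the median of the mitosis genes, of which only 2 of 33 lie in the span, was 0.90.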

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

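No test was made of either result in this part; both are signals in probe sets that the comparison of named genes does not use. All 18 probe sets for the bacterial and phage hybridisation controls had a higher signal on the array labelled EBP1, with a median log2 ratio of 0.39 (1.31-fold) and a range from 0.10 to 0.74. They cover only the control transcripts bioB, bioC, bioD and cre, each with several probe sets, so the 18 are not independent. Of 821 measured probe sets outside the platform's annotation table, 34 were at least 2-fold higher and 23 at least 2-fold lower on the array labelled EBP1, and of 643 that name several genes, 29 were higher and 18 lower by that much. Among the 7544 measured genes, 304 were higher and 268 lower by that much, or 7.58% together. The counts of both sets of probe sets are close to that share and do not stand out.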

How the results depend on the processing

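The removal of the chromosome 1 span was chosen after the data were seen; all other alternatives were planned. No paired analysis was possible because each group has 1 array, and for the same reason no array could be left out in turn. Apart from the fold threshold itself, the total number of genes past 2-fold moved most with the floor, which is where low signal over background limits it: 129 of the 572 genes rest on a signal below the floor on 1 array. A floor at the 25th percentile gave 1949 genes (1386 higher, 563 lower), no floor with a pseudocount of 16 gave 1814 (1248 and 566), and a floor at the 75th percentile gave 226 (106 and 120). Without probe sets ending in _s_at or _x_at there were 339 (178 and 161, with fewer genes measured), at 1.5-fold 1986 (1128 and 858) and at 3-fold 113 (59 and 54). Quantile normalization gave 574 genes and loess 568, sharing 94.1% and 92.3% of the 572 genes. With equal array medians the total was 689, but 148 genes were higher and 541 lower, and 72.7% of the 572 genes were shared. The medians of 6 of the 14 lists stayed outside their random range under all 8 alternatives of scaling, floor and probe sets: androgen-induced genes, E2F and DNA replication, mitosis, hypoxia and glycolysis, ATF4 and endoplasmic reticulum stress, and luminal markers. Another 6 lay inside it under some: androgen-repressed genes, ERBB genes, interferon-stimulated genes, cholesterol and fatty acid synthesis, heat shock, and TGF-beta and BMP targets. The last 2, prostate antigens and metallothioneins, lay outside it wherever at least 5 members were measured. Under the alternative scalings the random lists were rescaled too, so staying outside there could not decide about scaling. Without probe sets ending in _s_at or _x_at, 7 of 22 assessed lists were outside. With equal array medians the list medians were -0.87 for androgen-induced genes, 0.69 for androgen-repressed genes, -1.26 for prostate antigens, 0.57 for E2F and DNA replication, 0.65 for mitosis, -0.53 for interferon-stimulated genes, -0.81 for cholesterol and fatty acid synthesis, -1.09 for hypoxia and glycolysis, -0.74 for ATF4 and endoplasmic reticulum stress, 0.18 for heat shock, 0.66 for metallothioneins, 0.21 for TGF-beta and BMP targets and -0.73 for luminal markers. TGF-beta and BMP targets were at 0.35 after quantile normalization and 0.32 after loess, and interferon-stimulated genes at -0.42 after loess. With the floor at the 25th percentile prostate antigens were at -0.37, TGF-beta and BMP targets at 0.37 and ERBB genes at 0.0916, a change of direction. At the 75th percentile androgen-repressed genes were at 0.66, heat shock genes at 0.26 and TGF-beta and BMP targets at 0.69. With no floor prostate antigens were at -0.29, TGF-beta and BMP targets at 0.31 and ERBB genes at 0.33, again the other direction. The SD of a single probe set's log2 ratio, from pairs of the same gene, was 0.52 with no floor. With the median over probe sets ERBB genes were at -0.23, hypoxia and glycolysis genes at -1.04 and heat shock genes at 0.28. Without probe sets ending in _s_at or _x_at androgen-repressed genes were at 0.21, interferon-stimulated genes at -0.40, cholesterol and fatty acid synthesis at -0.32, hypoxia and glycolysis at -1.56, and ERBB genes turned to 0.48 with EGFR at 0.33. Of 81 named genes past 2-fold, 75 were still past it with equal array medians, 79 after quantile normalization or loess, 81 with the lower floor, 59 of the 76 still measured with the higher floor, and 76 with no floor or with the median over probe sets. Those lost with the higher floor, which shrinks ratios of dim genes, include ID1, ID2, OPRK1, PDK1, USP9Y, EGFR, LRIG1 and MSH6. PA2G4 stayed near 0, at -0.13 with equal medians and 0.20 after quantile normalization. Where no construction is named above, the cause was not tested.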

Other observations

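The tests of RNA integrity, of markers of another prostate line, of EBP1 transcript, of noise in Y-linked genes and of growth state, and the removal of the chromosome 1 span, were chosen only after the results were seen. Genes in several chromosomal places differed together between the arrays. Runs are made of windows of 30 neighbouring genes whose median lay further than the bound of 0.49 from the overall median of 0.07. On chromosome 1 there were such runs from SEC22B to PEX19 (125 genes, median log2 ratio 0.61) and from USP21 to ZNF692 (233 genes, 0.63), close neighbours within the same span, and on chromosome 5 a run from STK10 to CLK4 (31 genes) had a median of -0.42 as a whole. Of 9 measured Y-linked genes, 7 were lower on the array labelled EBP1 and 4 at least 2-fold: RPS4Y1, USP9Y, DDX3Y (254 to 3.79) and KDM5D (174 to 11.8). The other 2 were higher, UTY with 341 and 433 and LOC101929148 with 12.4 and 105. The probe set of UTY ends in _x_at and can bind transcripts of several genes.

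Among 12 measured genes of the cancer-testis families MAGE, GAGE, PAGE, XAGE, CTAG, SSX and CSAG, a group chosen after its values were seen, 4 were at least 2-fold higher on the array labelled EBP1 and 0 lower by that much, with a median log2 ratio of 0.04. PAGE1, MAGEC2 and CTAG2 were below the floor on the vector control array, and MAGEC1 was at least 2.30-fold higher. MAGEA6 (2742 and 2959), MAGEA12 (1978 and 2067), MAGEA1 (1486 and 1200.1) and MAGEA4 (1956 and 1506) were bright on both arrays and differed by less than 2-fold between them.

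Androgen-induced genes were lower on the array labelled EBP1. Other scalings did not remove the shift: over median, quantile and loess scaling the list median nearest to 0 was -0.61. The list median was outside the random range each time, but the random lists are rescaled with it, so that comparison could not decide about scaling. RNA degradation is argued against, as the ratio of 3′ to 5′ signal differed by at most 0.20 on the log2 scale. Cells of an androgen-receptor-negative prostate line are argued against by the low level of their markers, of which 11 of 15 were below the floor on both arrays and the brightest had a signal of 177 on the array labelled EBP1; 0 were at least 2-fold higher, but only 4 had a ratio. A repressing effect of EBP1 remains a candidate explanation, but with a largest PA2G4 log2 ratio of 0.15 and an unknown coverage of the plasmid's transcript it cannot be told apart from a difference between cultures that the plasmid did not cause.

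Y-linked genes were low on the array labelled EBP1. Noise of single probe sets is argued against: the 8 genes at or above the floor on the control array had a median log2 ratio of -0.97, below the range of -0.38 to 0.44 of random sets of like signal. Of the 8 genes, 7 were lower, while UTY was higher, with signals of 341 and 433. UTY was measured by 1 probe set, whose name ends in _x_at, so its signal may come from transcripts of other genes. Cultures of different chromosome content may account for the low Y-linked genes, since this explanation called in advance for runs of neighbouring genes on other chromosomes, and 3 runs were found, 2 of them in the same span of chromosome 1 and the last a short one on chromosome 5. Any such run would have met the prediction, and these runs do not show directly what became of the Y chromosome. Whether such a difference arose in selection of the pools or was there before was not tested.

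Mitosis genes were higher and hypoxia and glycolysis genes lower on the array labelled EBP1. The 3 other scalings did not remove either shift, with a median nearest to 0 of 0.65 over both lists. Both medians stayed outside their random ranges, but the random lists are rescaled too, so that comparison could not decide about scaling. Members of each list above and below its own median signal shifted the same way, by at least 0.82 in size (-0.82 for hypoxia and glycolysis). With all 33 mitosis genes higher and 21 of 23 hypoxia and glycolysis genes lower, that direction could hardly differ between the parts. The sizes could: the medians of the brighter and dimmer parts were 0.93 and 0.91 for mitosis. For hypoxia and glycolysis they were -0.92 and -0.82. These sizes argue against an effect in only the dim or only the bright part of each list. They do not cover the whole signal range of the arrays. Only 2 of the 33 mitosis genes lie in the chromosome 1 span, so the median without it (0.90) had little room to move; the span is argued against by the other members, which lie outside it and were all higher. The growth state of the cultures at harvest, such as density or oxygen supply, could also give both shifts, and with 1 culture per group it cannot be told apart from the plasmid for the mitosis median of 0.93.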
